A study of Mus musculus with 8 samples.

How the data were processed

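Total RNA of embryoid bodies of an inducible Tbx6 mouse embryonic stem cell line was measured on 8 single-colour Toray 3D-Gene oligonucleotide arrays, each read at 635 nm with the Cy5 dye. Per the labels' protocols, RNA was extracted with a column kit, amplified to amino allyl aRNA, coupled to the dye and fragmented. Samples were grouped by their titles into DoxOn_day2, DoxOFF_day2, DoxOn_day4 and DoxOFF_day4, with 2 arrays in each, and the replicate numbers 1 and 2 were taken from the titles. The labels name no culture, so whether the replicates are separate cultures is not given in the sources used here.

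The deposited scanner output gives for each spot a median intensity, a second median intensity given as background, and a quality flag. Per the file headers, both were scaled over 3 scanner gains by fitted lines, and neither is background-corrected. The scanner software and a genome build are not given in the sources used here, and no coordinates are printed. The authors also deposited a table of processed intensity values, whose steps no label states. Set against the scanner values, each column of that table was a straight line through the level of the blank spots (r = 1.00), scaled to a median of 25 on every array, on a linear scale, with dim and poor spots left empty, so that 21228 to 21676 probes per array have a value. It was used as an alternative after taking log2.

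The design written in advance called for normexp background correction (offset 50) on the local background, or for subtraction of the blank spots where no local background is given. The local background column followed the spot itself (correlation of logs 0.984 to 0.998), and on 80.6% to 85.6% of gene spots it lay above the level of the blank spots, so it was read as spot signal and not as background. The mean of the 2734 to 2736 unflagged blank spots of each array was subtracted in its place. That choice was made after the columns were compared and before any test was run, and the planned normexp setting was kept as an alternative. The values of 23473 gene probes, without control and blank spots and without the 0 to 4 gene spots per array that the scanner had marked as poor, were quantile normalized between arrays, set to a floor of 2.06 (the median over arrays of 2 blank SDs), and log2 transformed. The blank SD lay between 0.871 and 1.37 intensity units. A probe counted as above background on an array where its intensity exceeded the mean plus 2 SD of the blanks, and 21661 probes that did so on at least 2 arrays were tested, while 1812 were left out.

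Probes were named from the platform's annotation. Of the gene probes, 16631 have 1 gene symbol, 0 have several and 6842 have none here. Old symbols were brought to current ones with the synonyms in a RefSeq gene table (GRCm38.p6), which changed 3947, and 62 symbols that it does not hold were kept as given. Of the probes tested, 15624 had a symbol and 6037 had none. The unnamed ones are counted in the totals, where they made up 592 of the calls for Dox at day 2 and 1501 at day 4. Where a gene had several probes the one with the highest mean intensity stood for it, as for 205 symbols.

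Differences were tested with limma (version 3.58.1 in R 4.3.3): lmFit with 1 mean per group over all 8 arrays, contrasts for Dox at day 2, Dox at day 4, the difference between these, and time without and with Dox, then eBayes (residual df 4, prior df 2.70) and Benjamini-Hochberg adjustment over the probes tested, with a threshold of 0.05, 2-sided. Errors of log2 changes are standard errors of the fit. For a gene above background on no array of 1 group, the brighter group's mean was set against the higher of its own level and the lowest level above background on each array of the dimmer group, and given as at least N-fold. Fitted changes of such genes depend on the floor and are no bounds. The bounds rest on the blank spots. The negative control spots lay above the blank mean plus 2 SD on every array, and bounds set on them would be smaller. The 33 gene lists (589 genes) were tested with camera at a preset correlation of 0.01, 1 probe per gene, adjusted over the 33 lists within each comparison. Camera with an estimated correlation and fry were alternatives. Among lists that missed the threshold, the median and camera's direction differed in sign at day 2 for presomitic and paraxial mesoderm, cardiomyocyte contractile, smooth muscle, Notch and cholesterol synthesis genes, at day 4 for fibroblast, mesenchymal transition and Hox and Cdx genes, and for the difference for endothelial and blood and mesenchymal transition genes. They did so in no list that passed in these 3 comparisons. Fry tests whether a list's genes move on balance 1 way and compares the list with no other genes. Groups, lists, comparisons, most alternatives and the rule for named genes were set before the data were examined. JSON was read with jsonlite 2.0.0 and figures were drawn with matplotlib 3.10.9.

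The rule for named genes took Tbx6 and T always. For Dox at each day it took the 8 risen and the 8 fallen genes with the largest change among those with a symbol, an adjusted p under 0.05, no overlap between the arrays of the groups and both arrays of the higher group above background. From each list it took up to 4 members past the threshold with the largest change, or up to 2 where none passed, as values. For the difference between the days and for each course over time it took 5 in each direction. Genes named in the last part outside this rule were chosen after their values were seen.

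The fits were tested on simulated arrays built from the measured means and spread, with 200 probes changed by 1.5-fold (67 probes), 2-fold (67) or 4-fold (66). For Dox at day 2, 8.96%, 71.6% and 87.9% of these were recovered among 21675 probes, with 6 false calls. For Dox at day 4 it was 10.4%, 61.2% and 93.9% of the changed probes (21687 probes tested, 12 false calls). For the difference between the days it was 0%, 11.9% and 89.4% (21675 probes tested, 7 false calls). Without Dox over time it was 11.9%, 73.1% and 89.4% (21684 probes, 9 false calls), and with Dox 14.9%, 70.1% and 90.9% (21680 probes, 4). With nothing changed, limma made 0 calls in each of the 5 comparisons over 21686 probes. In the simulated test of the lists, the 1 list that was moved was called and 0 of the others were. The simulated noise was independent between probes and the lists were random. The simulation therefore does not test lists of correlated genes or camera's preset correlation. The 200 changed probes were also far fewer than those called in the data.

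The alternatives were median and 75th percentile scaling, the deposited processed table, no background correction, normexp on the local background, no filter on dim probes, probes above background on all 8 arrays, an intensity trend with robust variances, array weights, the replicate number as a block, fits of only the groups compared, a stricter threshold, a minimum change of 2-fold, the mean of a gene's probes, and leaving out each array in turn. Added after the data were seen were normexp on the blank spots, the scanner gain as a block, the crossed pairing at day 2, and a filter on the negative control spots. The scanner gain in the file headers fell into 2 levels. The slope was 0.464 to 0.467 for the 4 day-2 arrays and DoxOFF_day4 replicate 2, and 0.477 to 0.478 for the other 3.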

Results

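Gene expression was measured in embryoid bodies of a mouse embryonic stem cell line, named iTbx6 T-GFP in the labels, that was cultured with or without doxycycline (Dox), the inducer. Tbx6 encodes a T-box transcription factor of the primitive streak and presomitic mesoderm, and T encodes Brachyury, the T-box factor of the primitive streak. The cells were differentiated in serum-free medium to which no growth factors were added, and the comparisons set Dox against no Dox under these conditions. No cells without the transgene were given Dox among these samples. An effect of Dox itself therefore cannot be told apart from an effect of Tbx6 induction. RNA was taken at day 2 and at day 4, with and without Dox, and the labels do not state when Dox was added. Each of the 4 groups had 2 arrays, 8 arrays in all, and nothing in the labels says whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Each single-colour array held 23473 gene probes. The median gene probe intensity before background subtraction was 73.9 and 73.9 with Dox at day 2, 71.5 and 74.9 without, 80.9 and 82.6 with Dox at day 4 and 80.6 and 78.6 without, and the mean of the blank spots lay between 52.3 and 60.9. Between 20197 and 20927 gene probes per array (86.0% to 89.2%) were above the background set by the blank spots. The negative control spots lay above that background on every array, and between 17089 and 19011 gene probes were above these spots. Statements of a probe being above background, and changes given as at least N-fold, therefore hold against the blank spots only. The number of arrays limits the precision of every comparison.

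Arrays of the same group correlated at 0.993 or more across the 21661 probes kept for testing, and the highest correlation between groups was 0.985. The first principal component held 62.5% of the variance and set the day-4 arrays without Dox apart from all others. The second held 16.3% and separated the day-4 arrays labelled Dox-on from the rest. The values given here were corrected with the blank spots. With normexp on the scanner's local background column, which follows each spot's own brightness (correlation of logs 0.984 to 0.998), limma called 2 probes for Dox at day 2, 0 at day 4, 0 for the difference between the days, 0 without Dox and 3 with Dox over time. At an unadjusted p under 0.05 the same setting gave 479, 854, 527, 607 and 781 probes, and camera called 3, 2 and 3 lists for the first 3 comparisons. With no background correction at all, limma called 3292, 6809, 5601, 8294 and 4707 probes.

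**Figure D1:**
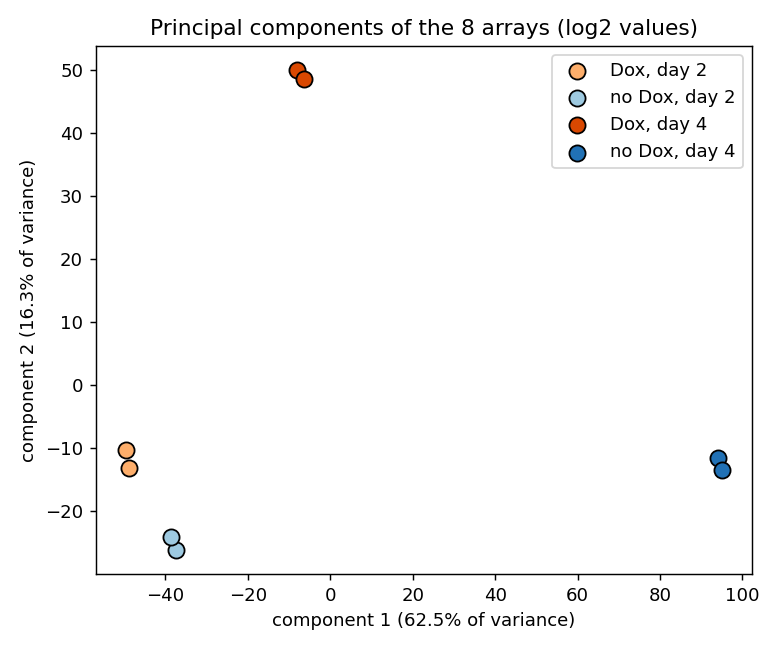
Positions of the 8 arrays on the first 2 principal components of their log2 values, with the share of variance on each axis (62.5% and 16.3%). Each point is 1 array, coloured by group, and the 2 arrays of each group lie next to each other.

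The Tbx6 probe was examined first in every sample. At day 2 its log2 intensity was 5.21 and 5.48 on the arrays labelled Dox-on and 5.59 and 5.49 on those labelled Dox-off. The log2 change was -0.20 ± 0.12 (SE, n = 2 arrays per group; limma adjusted p = 0.395). At day 4 the values were 6.10 and 6.23 with Dox and 5.50 and 5.58 without, a change of 0.62 ± 0.12 (limma adjusted p = 0.00915). That call ended without DoxOn_day4 replicate 2 (adjusted p = 0.0527) and without DoxOFF_day4 replicate 1 (adjusted p = 0.0508). The position of the probe in the transcript is not given in the sources used here. If it lies outside the inserted sequence it does not check the labels, so all directions below are those of the arrays as labelled. T did not pass the threshold at day 2 (log2 change 0.16 ± 0.11, adjusted p = 0.453) and rose 93.4-fold at day 4 (log2 change 6.55 ± 0.11, adjusted p = 4.6e-07).

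**Figure D2:**
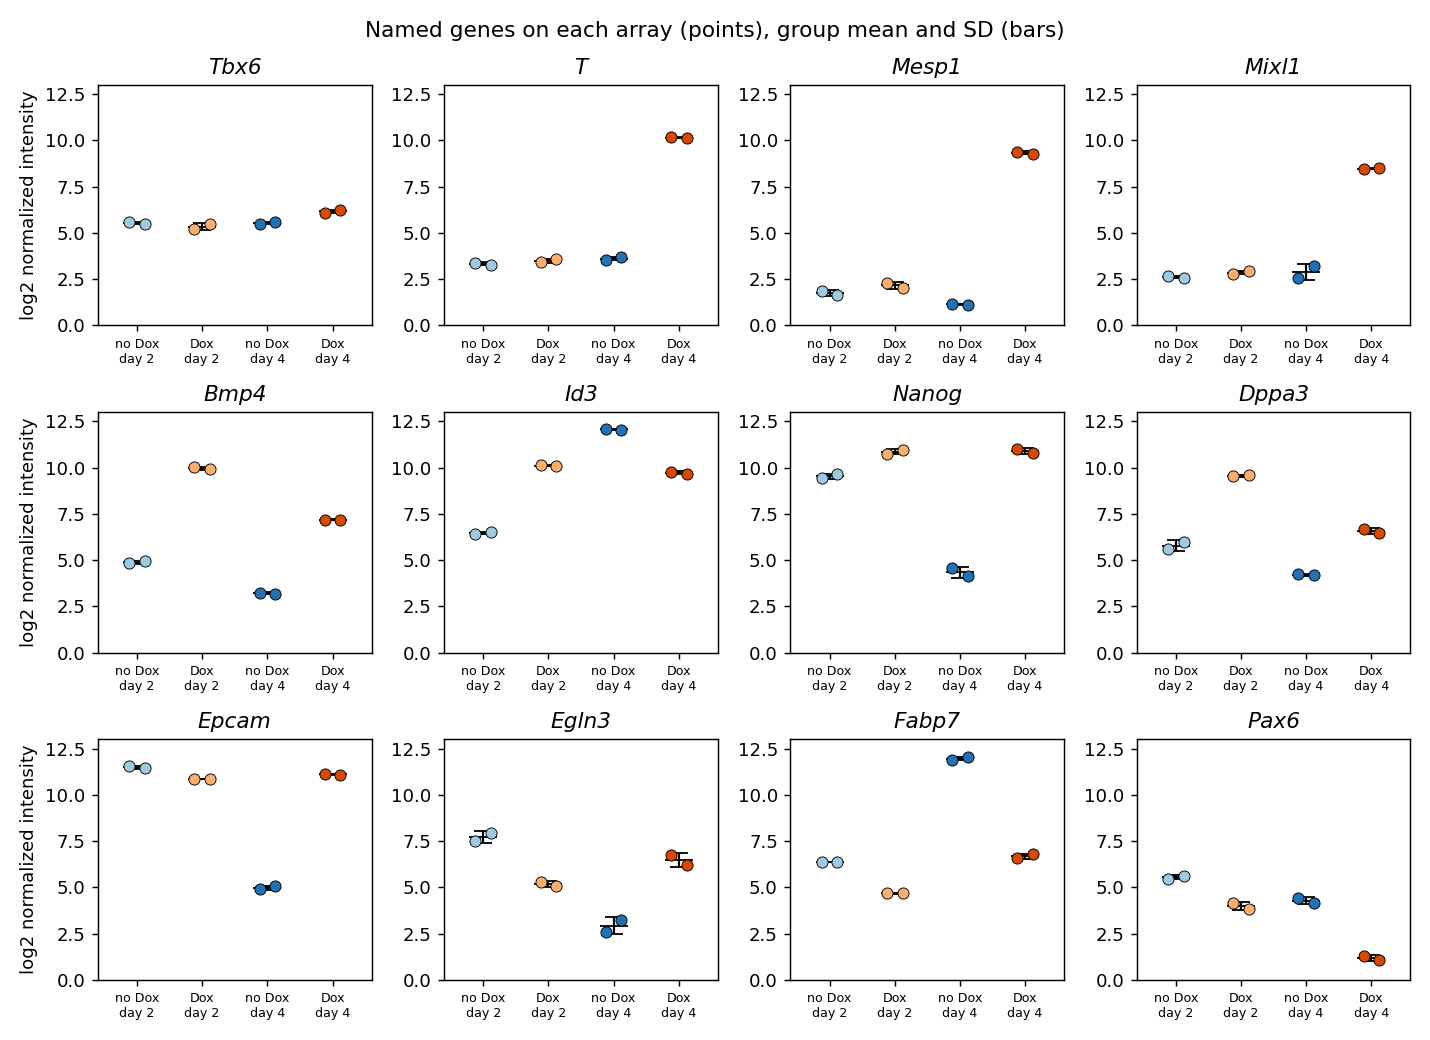
Log2 normalized intensity (vertical axis) of 12 named genes on each array, by Dox state and day (horizontal axis). Points are arrays, and bars give the group mean and SD (n = 2). T, Mesp1 and Mixl1 were high in the day-4 arrays labelled Dox-on, Bmp4 was higher with Dox at both days, and Id3 rose with Dox at day 2 and was lower with Dox at day 4.

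At day 2, the arrays labelled Dox-on were compared with those without Dox, although the length of exposure to Dox by then is not given. Rhox6, a homeobox gene of placenta and germ cells, rose 103-fold (log2 change 6.69 ± 0.25), and Bmp4, which encodes a bone morphogenetic protein, rose 34.0-fold (5.09 ± 0.10), from a mean log2 intensity of 4.88 ± 0.07 to 9.97 ± 0.09 (SD, n = 2). Ly6c1, a membrane-anchored surface protein gene, rose by 5.05 ± 0.17, and Tfap2c, a transcription factor gene of trophoblast and germ cells, by 4.99 ± 0.17. The other large rises were 3830417A13Rik (4.46), Cpsf4l (4.03), the tetraspanin gene Cd37, at least 15.4-fold, and the interferon-inducible GTPase gene Irgm1 (3.92). Adm, which encodes the vasoactive peptide adrenomedullin, was 71.9-fold lower (log2 change -6.17 ± 0.29), and the trypsin inhibitor gene Spink1 was 31.7-fold lower (-4.99 ± 0.20). The hormone and retinol carrier gene Ttr was at least 21.4-fold lower and the lipoprotein gene Apoa1 at least 8.91-fold lower. Pyy (-3.24), the egg receptor gene Izumo1r (-3.20), Stra8, a retinoic acid-induced gene of meiotic entry (-3.05), and Loxl2, a lysyl oxidase-like enzyme gene (-3.03), completed the largest falls. The adjusted p of these 16 genes was at most 0.00102 by limma. Of 21661 probes tested, 1203 were higher and 1354 lower with Dox at day 2, and 424 and 336 of them changed at least 2-fold. The count of 2557 fell to 1267 and 1191 without DoxOn_day2 replicate 1 or 2, to 1332 and 1541 without DoxOFF_day2 replicate 1 or 2, and to 1632 in a fit of the 4 day-2 arrays alone.

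Genes of BMP signalling rose at day 2. In the BMP pathway and targets list, 10 of 16 measured members rose and 0 fell (12 and 0 adjusted over the list alone). The median log2 change was 1.27, and the camera adjusted p was 1.2e-10 (adjusted p = 0.0599 with an estimated correlation). Besides Bmp4 the largest members were the inhibitor-of-DNA-binding genes Id1 (3.78 ± 0.16), Id3 (3.62 ± 0.10) and Id4 (2.69 ± 0.22). In the pluripotency list, 10 of 23 measured members rose and 0 fell (12 and 1 adjusted over the list alone), with a median log2 change of 0.46 and a camera adjusted p of 2.5e-06 (adjusted p = 0.0655 with an estimated correlation). Its largest changes were in Dppa3 (3.77 ± 0.16), a maternal and germ cell factor gene, Zfp42, which encodes Rex1 (2.51 ± 0.11), and the nuclear receptor genes Nr5a2 (2.42 ± 0.10) and Nr0b1 (1.43 ± 0.09). In the trophoblast list, 4 of 9 measured members rose and 1 fell (5 and 1 adjusted over the list alone), with a median log2 change of 0.29 and a camera adjusted p of 0.00130 (adjusted p = 0.111 with an estimated correlation). Elf5 rose by 2.77 ± 0.17 and Tead4 by 1.12 ± 0.14 beside Tfap2c. In the surface ectoderm and neural crest list, 4 of 12 measured members rose and 0 fell (4 and 0 adjusted over the list alone), with a median log2 change of 0.22 and a camera adjusted p of 0.00992 (adjusted p = 0.151 with an estimated correlation). Its largest changes were in Grhl3, an epidermal factor gene (2.30 ± 0.20), and in Msx2 (1.57 ± 0.20) and Msx1 (1.26 ± 0.15), which the BMP list also holds. In the cell cycle list, 2 of 25 measured members rose and 0 fell (0 and 0 adjusted over the list alone), with a median log2 change of 0.18 and a camera adjusted p of 0.00437 (adjusted p = 0.187 with an estimated correlation). Aurka (0.46 ± 0.11) and Ccnb2 (0.46 ± 0.10) passed over all probes, and both calls ended without any 1 of the 4 day-2 arrays, with adjusted p up to 0.196 for Aurka and 0.142 for Ccnb2. Aurka's call ended as well without either DoxOFF_day4 array, at adjusted p values of 0.0671 and 0.0674.

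The lists that fell at day 2 numbered 6 of 33. In the hypoxia and glycolysis list, 0 of 19 measured members rose and 12 fell (0 and 15 adjusted over the list alone). The median log2 change was -1.09, and the camera adjusted p was 1.5e-12 (adjusted p = 0.0655 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase gene, fell by 2.55 on the log2 scale, the glucose transporter gene Slc2a1 by 2.35, and the glycolytic enzyme genes Aldoc, Tpi1 and Pgk1 by 1.61, 1.53 and 1.38. In the primitive and visceral endoderm list, 1 of 17 measured members rose and 7 fell (1 and 10 adjusted over the list alone), with a median log2 change of -0.58 and a camera adjusted p of 1.7e-04 (adjusted p = 0.0930 with an estimated correlation). Beside Spink1, Ttr and Apoa1, the endocytic adaptor gene Dab2 changed by -2.12 ± 0.33. In the epithelial list, 0 of 16 measured members rose and 6 fell (1 and 8 adjusted over the list alone), with a median log2 change of -0.34 and a camera adjusted p of 0.00272 (adjusted p = 0.111 with an estimated correlation). The tight junction genes Ocln (-0.87 ± 0.19) and Cldn7 (-0.71 ± 0.11) and the adhesion gene Epcam (-0.64 ± 0.10) were lower. Ocln's call ended without either DoxOFF_day2 array, DoxOn_day2 replicate 2 or either DoxOn_day4 array (adjusted p up to 0.163), Epcam's without either DoxOn_day2 array or DoxOFF_day2 replicate 1 (up to 0.0598), and Cldn7's without DoxOn_day2 replicate 2 (0.0541). In the primed epiblast list, 0 of 9 measured members rose and 4 fell (0 and 6 adjusted over the list alone), with a median log2 change of -0.36 and a camera adjusted p of 0.00381 (adjusted p = 0.151 with an estimated correlation), with Zic2 at -1.06 ± 0.10. In the neural list, 0 of 23 measured members rose and 5 fell (1 and 8 adjusted over the list alone), with a median log2 change of -0.23 and a camera adjusted p of 0.0137 (adjusted p = 0.187 with an estimated correlation). The radial glia gene Fabp7 (-1.69 ± 0.11), the eye and forebrain factor gene Pax6 (-1.55 ± 0.16) and Stmn2 (-0.87 ± 0.11) were lower. In the housekeeping list, 1 of 11 measured members rose and 4 fell (1 and 5 adjusted over the list alone), with a median log2 change of -0.30 and a camera adjusted p of 0.0422 (adjusted p = 0.187 with an estimated correlation). Pgk1 stands in this list as well as among the glycolytic genes. The brighter of 2 Actb probes rose by 0.90 ± 0.16 and the other gave 0.07 (adjusted p = 0.854). Actb's call ended without either DoxOFF_day2 array (adjusted p up to 0.0654). In a fit of the 4 day-2 arrays alone the calls of Actb, Aurka, Ccnb2, Dab2 and Ocln and of the housekeeping list ended (adjusted p between 0.0513 and 0.0823). The housekeeping call ended also without any 1 of the 4 day-2 arrays (adjusted p up to 0.0735), and the neural one without DoxOn_day2 replicate 1 or DoxOFF_day2 replicate 1 (up to 0.0514). With an estimated correlation camera called 0 of 33 lists at day 2 (lowest adjusted p = 0.0599), against 11 with the preset one and 19 by fry.

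Mesoderm lists did not pass the threshold at day 2. In the primitive streak and nascent mesoderm list 1 of 19 rose and 3 fell (1 and 3 adjusted over the list alone; median 0.22; camera adjusted p = 0.460, and adjusted p = 0.737 with an estimated correlation), and the ligand gene Apln changed by -1.53 ± 0.23, a call that ended without DoxOn_day2 replicate 2 (adjusted p = 0.0519) and with no background correction (log2 change -0.13, adjusted p = 0.279). In the cardiac and lateral plate mesoderm list 1 of 23 rose and 2 fell (1 and 2 adjusted over the list alone; median 0.08; camera adjusted p = 0.464, and adjusted p = 0.589 with an estimated correlation), where the receptor gene Pdgfra changed by -2.50 ± 0.12 and the transcription factor gene Gata6 by -1.42 ± 0.21. In the presomitic and paraxial mesoderm list 2 of 23 rose and 2 fell (2 and 2 adjusted over the list alone; median -0.05; camera adjusted p = 0.930, and adjusted p = 0.953 with an estimated correlation), with the transcriptional co-regulator gene Cited1 at 2.92 ± 0.19. In the heat shock and unfolded protein response list 4 of 13 rose and 3 fell (4 and 5 adjusted over the list alone; median -0.02; camera adjusted p = 0.873, and adjusted p = 0.940 with an estimated correlation). Ddit3, which encodes the stress-induced factor CHOP, changed by -2.91 ± 0.13 and the small heat shock protein gene Hspb1 by 0.99 ± 0.12.

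At day 4, 2 days after dissociation and reaggregation, the same comparison showed genes of the primitive streak, early mesoderm and pluripotency far higher in the arrays labelled Dox-on. Mesp1, a basic helix-loop-helix factor gene of the earliest cardiac progenitors, was at least 267-fold higher, with a mean log2 intensity of 9.33 ± 0.09 with Dox and 1.14 ± 0.05 without, where it was not above background (SD, n = 2). Utf1, a chromatin-associated gene of embryonic stem cells, rose 158-fold (log2 change 7.30 ± 0.10), and Tdgf1, which encodes the Nodal co-receptor Cripto, rose 141-fold (7.14 ± 0.18). The actin-binding smooth muscle gene Tagln rose by 7.02 ± 0.26, the synaptonemal complex gene Sycp3 by 6.74 ± 0.30, the zinc-finger factor gene Bcl11a by 6.66 ± 0.17, and the pluripotency genes Dppa5a and Nanog by 6.58 ± 0.10 and 6.56 ± 0.18. The largest falls were in Pdzph1, at least 476-fold lower, Lrtm1, at least 83.1-fold, and Wfdc1, at least 60.3-fold. Msx3, a homeobox gene of the dorsal neural tube, changed by -6.34 ± 0.25, the retinoic acid-binding protein genes Crabp2 and Crabp1 by -6.33 ± 0.21 and -5.36 ± 0.13, the growth factor gene Ptn by -5.67 ± 0.11, and Pou3f4, a neural POU-domain factor gene, by -5.31 ± 0.11. The adjusted p of these 16 genes was at most 1.1e-05 by limma. Of 21661 probes, 3117 were higher and 3366 lower, 1292 and 1079 of them at least 2-fold.

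Lists of the primitive streak, of cardiac and smooth muscle genes, of Nodal, FGF and BMP signalling and of definitive endoderm were higher with Dox at day 4. In the primitive streak and nascent mesoderm list, 16 of 19 measured members rose and 0 fell (16 and 1 adjusted over the list alone). The median log2 change was 3.55, and the camera adjusted p was 4.7e-13 (adjusted p = 0.0724 with an estimated correlation). Beside T and Mesp1, the activin antagonist gene Fst rose by 5.70 ± 0.17 and the homeobox gene Mixl1 by 5.59 ± 0.20. In the cardiac and lateral plate mesoderm list, 8 of 23 measured members rose and 2 fell (9 and 3 adjusted over the list alone), with a median log2 change of 0.27 and a camera adjusted p of 0.0129 (adjusted p = 0.0997 with an estimated correlation). Bmp4 (3.96 ± 0.10), the apelin receptor gene Aplnr (3.39 ± 0.11) and Pdgfra (2.19 ± 0.12) rose with Mesp1, and the list's call ended when probes had to be above background on all 8 arrays (adjusted p = 0.0917), which removes Mesp1. In the cardiomyocyte contractile list, 6 of 18 measured members rose and 0 fell (6 and 0 adjusted over the list alone), with a median log2 change of 0.23 and a camera adjusted p of 0.0158 (adjusted p = 0.183 with an estimated correlation). The atrial myosin light chain gene Myl7 rose 4.0-fold and the tropomyosin gene Tpm1 3.91-fold. With genes not above background in a whole group set at their bound or, where neither group was above it, at 0, the median was 0.18, and no other list that passed at day 4 moved. That list's call ended without DoxOn_day4 replicate 1, where its adjusted p was 0.050. In the smooth muscle list, 7 of 12 measured members rose and 0 fell (7 and 0 adjusted over the list alone). The median log2 change was 1.40, and the camera adjusted p was 3.1e-04 (adjusted p = 0.0724 with an estimated correlation). After Tagln the largest members were Cnn1 (4.91 ± 0.19) and Acta2 (3.08 ± 0.16). In the Nodal and TGF-beta list, 8 of 13 measured members rose and 0 fell (8 and 0 adjusted over the list alone), with a median log2 change of 1.81 and a camera adjusted p of 3.0e-05 (adjusted p = 0.0724 with an estimated correlation). Its largest change was in Tdgf1, which the pluripotency list also holds. The ligand genes Gdf3 (4.53 ± 0.14) and Nodal (4.26 ± 0.13) and the antagonist gene Lefty1 (4.17 ± 0.14) rose too. In the FGF and ERK targets list, 11 of 17 measured members rose and 2 fell (11 and 2 adjusted over the list alone), with a median log2 change of 0.64 and a camera adjusted p of 6.0e-04 (adjusted p = 0.0724 with an estimated correlation), with Fgf5 at 4.65 ± 0.11 and the phosphatase gene Dusp6 at 2.06 ± 0.10. In the BMP list, 7 of 16 measured members rose and 1 fell (10 and 2 adjusted over the list alone), with a median log2 change of 0.48 and a camera adjusted p of 0.00628 (adjusted p = 0.0988 with an estimated correlation). Smad7 rose by 2.98 ± 0.16 whereas Id3 changed by -2.35 ± 0.10. In the definitive endoderm list, 6 of 13 measured members rose and 1 fell (6 and 1 adjusted over the list alone), with a median log2 change of 0.55 and a camera adjusted p of 0.0129 (adjusted p = 0.0997 with an estimated correlation). Lhx1 (4.93 ± 0.09), which the primitive streak list also holds, and Foxa2 (3.20 ± 0.23) rose and the chemokine receptor gene Cxcr4 fell (-1.69 ± 0.19).

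Pluripotency and epithelial genes were the groups whose shift at day 4 also passed with an estimated correlation. In the pluripotency list, 19 of 23 measured members rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 change of 2.42 and a camera adjusted p of 1.7e-13 (adjusted p = 0.0184 with an estimated correlation), led by Utf1, Tdgf1, Dppa5a and Nanog. In the epithelial list, 15 of 16 measured members rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 change of 2.84 and a camera adjusted p of 1.7e-13 (adjusted p = 0.0184 with an estimated correlation). Epcam (6.12 ± 0.10), the splicing regulator gene Esrp1 (6.04 ± 0.10), the basolateral sorting gene Ap1m2 (5.69 ± 0.13) and the claudin gene Cldn6 (5.68 ± 0.11) had the largest changes. From day 2 to day 4 without Dox, 1 of 23 pluripotency genes rose and 17 fell (median log2 change -2.65). Of 16 epithelial genes, 0 rose and 14 fell (-2.55). Camera adjusted p was 2.9e-11 for each, and 0.0269 with an estimated correlation. With Dox, 2 pluripotency genes rose and 14 fell over that time. The rises at day 4 are differences from arrays without Dox, where both lists had fallen. In the hypoxia and glycolysis list, 15 of 19 measured members rose and 1 fell (15 and 1 adjusted over the list alone), with a median log2 change of 0.59 and a camera adjusted p of 3.2e-06 (adjusted p = 0.0942 with an estimated correlation). Egln3 rose by 3.54 ± 0.28 and the phosphofructokinase gene Pfkp by 3.50 ± 0.10, and Slc2a1 was the member that fell (-1.19 ± 0.10). In the heat shock and unfolded protein response list, 10 of 13 measured members rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 change of 0.94 and a camera adjusted p of 1.7e-04 (adjusted p = 0.0997 with an estimated correlation), with Hspb1 at 4.31 ± 0.12 and Chac1, a stress-induced glutathione-degrading enzyme gene, at 2.36 ± 0.12. In the list of cell cycle inhibitors and p53 targets, 7 of 15 measured members rose and 1 fell (9 and 1 adjusted over the list alone), with a median log2 change of 0.65 and a camera adjusted p of 0.0129 (adjusted p = 0.0997 with an estimated correlation). The apoptosis gene Pmaip1 rose by 3.74 ± 0.10 and the cyclin-dependent kinase inhibitor gene Cdkn1a by 1.25 ± 0.13. In the trophoblast list, 4 of 9 measured members rose and 0 fell (4 and 0 adjusted over the list alone), with a median log2 change of 0.61 and a camera adjusted p of 0.00283 (adjusted p = 0.0942 with an estimated correlation). Its largest members were Eomes (3.55 ± 0.11), which the primitive streak list also holds, and Tfap2c (3.39 ± 0.17).

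Neural genes were lower with Dox at day 4. In the neural list, 1 of 23 measured members rose and 13 fell (1 and 14 adjusted over the list alone). The median log2 change was -0.62, and the camera adjusted p was 4.7e-05 (adjusted p = 0.0724 with an estimated correlation). Fabp7 changed by -5.29 ± 0.11, the transcription factor genes Irx3, Pou3f2 and Pax6 by -3.23 ± 0.14, -3.15 ± 0.19 and -3.10 ± 0.16, and Stmn2 was the member that rose (1.51 ± 0.11). In the Notch list, 2 of 15 measured members rose and 9 fell (3 and 9 adjusted over the list alone), with a median log2 change of -0.71 and a camera adjusted p of 0.0398 (adjusted p = 0.155 with an estimated correlation). Lfng (-3.43 ± 0.20), the target gene Hes5 (-2.72 ± 0.15) and the ligand gene Jag1 (-2.53 ± 0.14) fell while the ligand gene Dll3 rose (1.76 ± 0.11). The Notch call ended without DoxOFF_day4 replicate 1 (adjusted p = 0.0628) and under 2 of the 3 other filters (adjusted p = 0.0807 with no filter and 0.115 with probes above background on all 8 arrays). In the cholesterol synthesis list, 0 of 10 measured members rose and 5 fell (0 and 5 adjusted over the list alone), with a median log2 change of -0.54 and a camera adjusted p of 0.0118 (adjusted p = 0.188 with an estimated correlation), with Nsdhl at -1.31 ± 0.09 and Dhcr7 at -1.26 ± 0.21. In the cell cycle list, 0 of 25 measured members rose and 8 fell (0 and 8 adjusted over the list alone), with a median log2 change of -0.25 and a camera adjusted p of 0.0138 (adjusted p = 0.185 with an estimated correlation). The replication genes Pcna (-0.75 ± 0.17) and Rrm2 (-0.66 ± 0.11) were lower, and Pcna's call ended without DoxOn_day4 replicate 1, DoxOFF_day4 replicate 1 or DoxOFF_day4 replicate 2 (adjusted p up to 0.0828). Of the 33 lists, 18 passed at day 4 with the preset correlation, 2 with an estimated one and 26 by fry. The scanner gain in the file headers split the arrays 3 to 5. DoxOFF_day4 was the only group with arrays at both levels, its replicate 2 standing with the day-2 arrays. A block on the gain thus cannot tell gain from a difference between these replicates. It gives the same day-4 changes with Dox as leaving out DoxOFF_day4 replicate 2, so the 2 settings are not separate checks. With the gain as a block 4673 probes and 19 lists passed at day 4, and without that array 4627 probes and 18 lists did.

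Genes of other mesodermal fates moved both ways, and 11 lists passed camera's threshold at neither day. The presomitic and paraxial mesoderm list had a median log2 change of -0.05 at day 2 (adjusted p = 0.930) and -0.20 at day 4 (0.625), and 4 of 23 rose and 5 fell at day 4 (4 and 5 adjusted over the list alone). The receptor gene Epha1 rose by 4.84 ± 0.11, while the paired-box gene Pax3 (-3.37 ± 0.22) and the ligand gene Dll1 (-1.88 ± 0.13) fell. The endothelial and blood list was at 0.00 at day 2 (adjusted p = 0.464) and 0.18 at day 4 (0.0769), and 5 of 21 rose and 1 fell at day 4 (5 and 1 adjusted over the list alone), among them Flt1 (3.01 ± 0.36), Etv2 (2.79 ± 0.19) and Lmo2 (2.65 ± 0.10). The mesenchymal transition list was at 0.06 at day 2 (adjusted p = 0.510) and 0.04 at day 4 (0.660), and 3 of 17 rose and 6 fell at day 4 (3 and 6 adjusted over the list alone), with N-cadherin, Cdh2, at -2.58 ± 0.10. The retinoic acid list was at -0.05 at day 2 (adjusted p = 0.128) and -0.15 at day 4 (0.770), where Crabp1 and Crabp2 fell and the retinoic acid-degrading enzyme gene Cyp26a1 rose by 4.77 ± 0.21. The Wnt targets were at -0.04 at day 2 (adjusted p = 0.497) and 0.06 at day 4 (0.532), and 3 of 17 rose and 3 fell at day 4 (3 and 3 adjusted over the list alone), T among them.

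The Hox and Cdx list was at -0.07 at day 2 (adjusted p = 0.286) and -0.02 at day 4 (0.950) and skeletal muscle at -0.20 at day 2 (adjusted p = 0.0526) and 0.14 at day 4 (0.532). Chondrogenic genes were at 0.06 at day 2 (adjusted p = 0.440) and -0.08 at day 4 (0.419). The fibroblast markers, included because feeder cells can remain in stem cell cultures, were at -0.11 at day 2 (adjusted p = 0.0506) and -0.07 at day 4 (0.950). Ribosomal protein genes were at -0.08 at day 2 (adjusted p = 0.505) and 0.04 at day 4 (0.532) and oxidative phosphorylation genes at -0.01 at day 2 (adjusted p = 0.930) and 0.20 at day 4 (0.0765). The fibroblast list passed as lower at day 2 with median scaling (adjusted p = 0.0438), with probes above background on all 8 arrays (0.0309) and with the negative control filter (0.0302). It also passed with the replicate block (0.0456), the scanner-gain block (0.0421), array weights (0.0492) and a fit of the day-2 arrays alone (0.0419). Without DoxOFF_day2 replicate 2 or either DoxOFF_day4 array it passed at 0.00728 to 0.0427, and over all alternatives its adjusted p ran from 0.00728 to 0.826. Skeletal muscle passed at day 2 with median scaling (0.0438) and without DoxOFF_day2 replicate 2 (0.0436), in a range from 0.00332 to 0.826. Oxidative phosphorylation passed as higher at day 4 with the deposited values (0.0470), no background correction (0.0253), normexp on the blank spots (0.0259) and no filter on dim probes (0.0362). It passed too with the scanner-gain block (0.0466) and without DoxOn_day4 replicate 1 (0.0456), in a range from 0.00597 to 0.387. The endothelial and blood list passed as higher at day 4 with the deposited values (0.0470), the negative control filter (0.0298) and a fit of the day-4 arrays alone (0.0438). Without DoxOFF_day4 replicate 1 or DoxOn_day4 replicate 2 it passed at 0.0423 and 0.0449, in a range from 1.3e-04 to 0.432. The retinoic acid list passed as lower at day 2 without DoxOn_day2 replicate 1 (0.0488), in a range from 0.00185 to 0.733. Of the definitive endoderm genes at day 2, 1 of 13 rose and 4 fell (1 and 4 adjusted over the list alone; median -0.27; camera adjusted p = 0.0799, and adjusted p = 0.224 with an estimated correlation). It passed as lower there with the deposited values (0.0470) and with probes above background on all 8 arrays (0.0309), in a range from 0.00433 to 0.826. Ribosomal proteins passed at day 2 with each of the 3 other scalings, where the median lay between -0.21 and -0.20. Each of these 7 lists passed by fry at the day given, and none with an estimated correlation. Other lists that passed by fry alone were cardiac and lateral plate mesoderm, endothelial and blood, and cell cycle inhibitors and p53 targets at day 2. At day 4 they were primed epiblast, chondrogenic, mesenchymal transition, Wnt targets, retinoic acid and ribosomal proteins. The primed epiblast list, which had fallen at day 2, was at 0.70 at day 4 (adjusted p = 0.164), the primitive and visceral endoderm list at -0.07 (0.950), surface ectoderm and neural crest genes at 0.10 (0.864), and housekeeping genes at 0.00 (0.931), although the housekeeping gene Hprt rose by 1.87 ± 0.09.

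**Figure D3:**
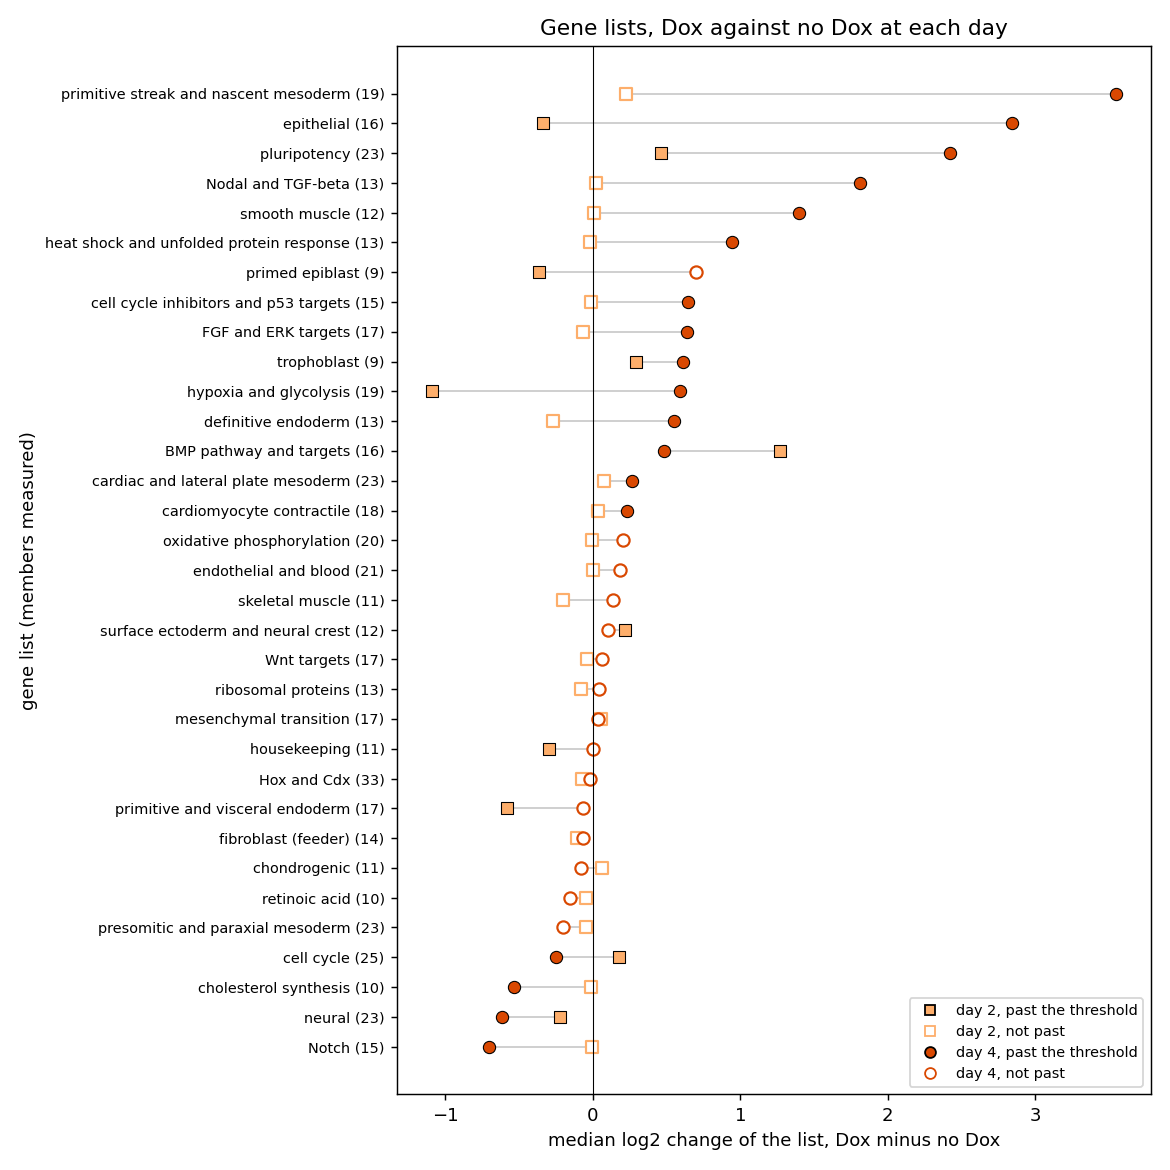
Median log2 change with Dox (horizontal axis) of each of the 33 gene lists (vertical axis, with the number of measured members) at day 2 (squares) and day 4 (circles), filled where camera's adjusted p was under 0.05 with the preset correlation. The hypoxia and glycolysis list lay at -1.09 at day 2 and 0.59 at day 4, and the primitive streak list moved from 0.22 to 3.55.

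Whether the response to Dox differed between the days was tested as an interaction. Adm, Sycp3, Bcl11a, Mesp1 and Tdgf1 had the largest positive differences (day 4 minus day 2): 9.40 ± 0.40, 8.19 ± 0.42, 7.96 ± 0.25, 7.79 ± 0.20 and 7.56 ± 0.26 on the log2 scale. Adm fell with Dox at day 2 and rose at day 4. Pdzph1 (-8.39 ± 0.18), Lrtm1 (-6.38 ± 0.13), Id3 (-5.98 ± 0.13), Msx3 (-5.93 ± 0.36) and Wfdc1 (-5.91 ± 0.13) had the largest negative ones. Limma adjusted p was at most 8.7e-05 for these 10 genes, and where a group was not above background (Mesp1, Pdzph1, Lrtm1, Wfdc1) the difference is a fitted value and no bound. The difference passed for 4794 of 21661 probes, 2414 more positive at day 4 and 2380 more negative. By list, 18 of 33 differed between the days, 13 upward and 5 downward, led by the epithelial genes (median difference 3.34, camera adjusted p = 1.2e-14, and adjusted p = 0.0311 with an estimated correlation, the only list to pass that way, while 30 passed by fry).

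The overlap of the changes with Dox at the 2 days was counted per direction. These comparisons share no arrays, but they share each probe's estimate of the spread. A probe with a small spread is more easily called at both days, so the counts in independent lists are only a rough guide. Probes higher at both days numbered 528 (173 in independent lists of these sizes; odds ratio 5.40), Bmp4, Tfap2c and Dppa3 among them. Those lower at both days numbered 430 (210 in independent lists; odds ratio 2.75), among them Fabp7 and Pax6. A further 414 were lower at day 2 and higher at day 4, more than the 195 of independent lists (odds ratio 2.87), and included Adm, Egln3 and Pdgfra. The 192 that were higher at day 2 and lower at day 4, such as Id3, were close to the 187 of independent lists (Fisher's exact test, adjusted over 4 directions, p = 0.682). Changes at the 2 days correlated at 0.0894 (Spearman) across probes, which are not independent replicates. The 958 probes called in 1 direction at both days fell to 519 and 481 without DoxOn_day2 replicate 1 or 2, and to 550 and 567 without DoxOFF_day2 replicate 1 or 2.

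**Figure D4:**
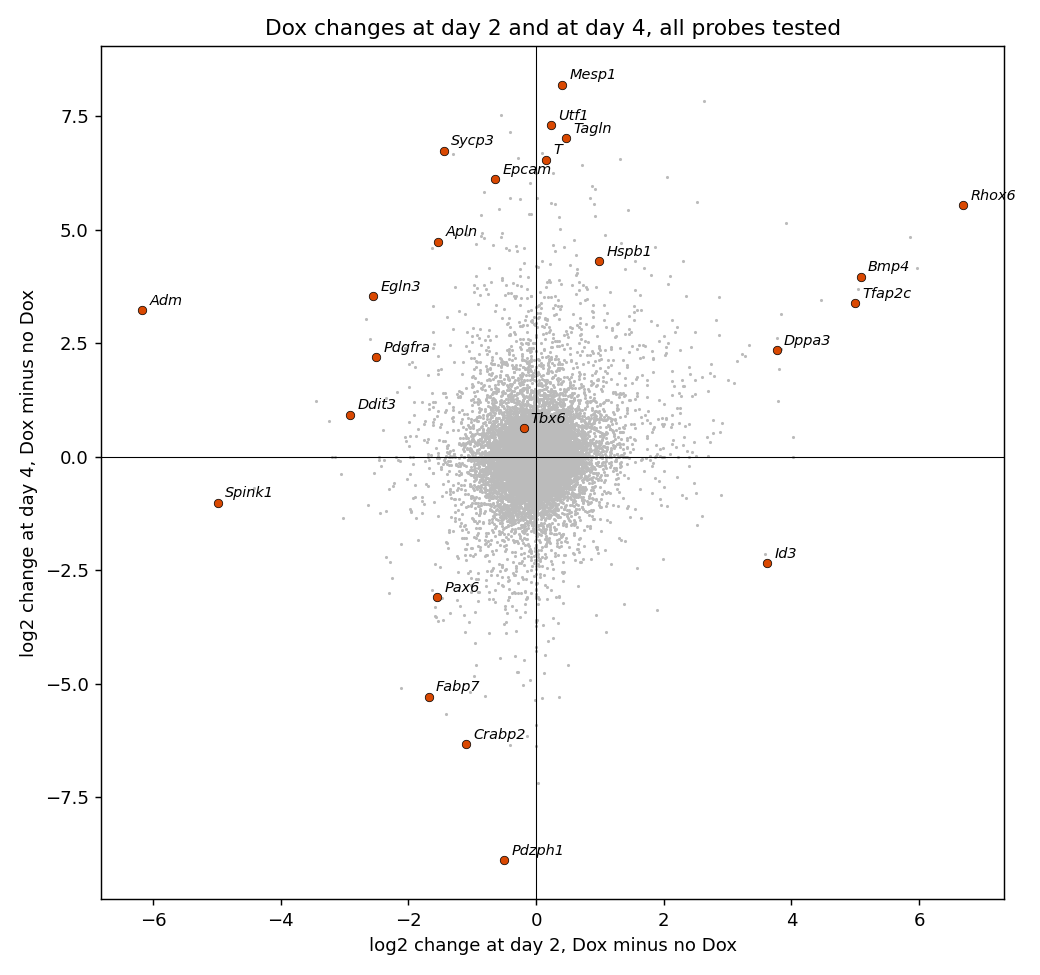
Log2 change with Dox at day 2 (horizontal axis) against that at day 4 (vertical axis) for the 21661 probes tested (grey), with named genes marked. Bmp4, Tfap2c and Rhox6 lie high on both axes, Mesp1, Utf1 and T on the day-4 axis, and Adm, Egln3 and Pdgfra below 0 at day 2 and above 0 at day 4.

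The course without Dox was followed from day 2 to day 4. Pdzph1 rose 138-fold (log2 change 7.10 ± 0.12), the forebrain homeobox gene Otx1 79.4-fold (6.31 ± 0.11) and Msx3 66.6-fold (6.06 ± 0.25), while Lrtm1 rose at least 78.8-fold and Wfdc1 at least 57.2-fold. Utf1 fell 636-fold (-9.31 ± 0.10), Dppa5a 406-fold (-8.67 ± 0.10), Sycp3 fell by 8.04 ± 0.30 on the log2 scale, the phospholipase gene Pla2g10 at least 186-fold, and Nupr1, a stress-induced chromatin protein gene, fell by 7.58 ± 0.13. Limma adjusted p was at most 6.5e-06 for these 10 genes. In all, 4383 probes rose and 3880 fell.

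With Dox, the 5 genes that rose most from day 2 to day 4 were Mesp1, T, Mixl1, Tagln and Apln. Mesp1 rose 144-fold (log2 change 7.17 ± 0.14), T 102-fold (6.67 ± 0.11), Mixl1 49.4-fold (5.63 ± 0.20), Tagln 44.3-fold (5.47 ± 0.26) and Apln 36.6-fold (5.19 ± 0.23). Calml4 (-4.77 ± 0.23), Zscan4c, a gene of the early embryo's 2-cell stage (-4.36 ± 0.12), the folate receptor gene Folr1 (-3.80 ± 0.14) and the protease gene Capn3 (-3.64 ± 0.10) fell most, with Cd37 at least 16.2-fold lower. Limma adjusted p was at most 6.0e-05 for these 10 genes. The comparison called 2087 probes higher and 2021 lower at day 4. That total of 4108 fell to 2609 and 2419 without DoxOn_day2 replicate 1 or 2, to 2691 and 2605 without DoxOn_day4 replicate 1 or 2, and to 1342 with the scanner-gain split as a block.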

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

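The comparison of partner arrays, the reading of the Tbx6 probe's own change and the count of pluripotency genes that did not fall were tests chosen only after the result was seen. The change with Dox differed between day 2 and day 4, by limma's test of the difference, for 4794 of 21661 probes and for 111 of the 118 named genes. Apart from Tbx6 and T, those genes were chosen for a large change with Dox at a day, a large difference between the days or a large change over time, so their share says little about other genes. In 28 of the named genes the calls at the days were opposite. Adm (9.40), Sycp3 (8.19), Bcl11a (7.96), Epcam (6.76), Pla2g10 (6.64), Apln (6.27), Nupr1 (6.23), Egln3 (6.09), Cnn1 (6.02), Lhx1 (5.46), Epha1 (5.39), Pmaip1 (5.02), Pdgfra (4.69), Cldn7 (4.57), Foxa2 (4.42), Pyy (4.03), Ddit3 (3.83), Lmo2 (3.40), Ocln (3.33), Gata6 (2.82), Aldoc (2.72), Myl7 (2.56), Stmn2 (2.38), Tpi1 (1.89) and Zic2 (1.76) fell with Dox at day 2 and rose at day 4 (log2 difference, day 4 minus day 2, in parentheses). Id3 (-5.98), Calml4 (-2.08) and Folr1 (-1.96) rose at day 2 and fell at day 4.

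Of the gene lists, 18 differed between the days by camera with the preset correlation. The median difference was positive for epithelial (3.34), primitive streak and nascent mesoderm (3.26), hypoxia and glycolysis (1.80), primed epiblast (1.76), pluripotency (1.73), heat shock and unfolded protein response (1.34), Nodal and TGF-beta (1.26), smooth muscle (0.99), primitive and visceral endoderm (0.65), definitive endoderm (0.64), FGF and ERK targets (0.60), cell cycle inhibitors and p53 targets (0.33) and cardiomyocyte contractile (0.20). It was negative for Notch (-0.57), neural (-0.51), cell cycle (-0.41), cholesterol synthesis (-0.34) and BMP pathway and targets (-0.31). With an estimated correlation only the epithelial list passed (adjusted p = 0.0311), and the calls for BMP, cholesterol synthesis, cardiomyocyte, primed epiblast and Notch genes each ended without at least 1 array. The adjusted p then lay between 0.0519 and 0.0599 for BMP (every array but DoxOn_day2 replicate 2 and DoxOFF_day4 replicate 2) and between 0.0516 and 0.0701 for cholesterol synthesis (DoxOn_day2 replicate 1, DoxOFF_day2 replicate 1, DoxOn_day4 replicate 2 and DoxOFF_day4 replicate 2). It was 0.0562 to 0.0575 for cardiomyocyte genes (DoxOFF_day2 replicate 1 and DoxOn_day4 replicate 1), 0.0538 to 0.0562 for primed epiblast (DoxOFF_day2 replicate 1 and DoxOn_day4 replicate 2) and 0.0531 for Notch (DoxOFF_day4 replicate 1). Other settings that ended a call were probes above background on all 8 arrays for primitive and visceral endoderm (adjusted p = 0.129), Notch (0.0845) and BMP (0.0528), and no filter on dim probes for Notch (0.0704), BMP (0.0582) and primed epiblast (0.0582). The BMP call also ended with median scaling (0.0568), the negative control filter (0.0535) and the replicate block (0.0566), that of primed epiblast with 75th percentile scaling (0.0508) and that of cholesterol synthesis with the scanner-gain block (0.0553). Over all alternatives the adjusted p ran from 1.9e-04 to 0.591 for primitive and visceral endoderm, 2.4e-05 to 0.429 for Notch, 4.0e-06 to 0.168 for BMP, 1.2e-05 to 0.182 for primed epiblast and 0.00223 to 0.778 for cholesterol synthesis. The skeletal muscle, oxidative phosphorylation, ribosomal protein and surface ectoderm lists passed by camera only under some other settings, and over all alternatives their adjusted p ran from 0.00329 to 0.448, 0.0138 to 0.398, 4.8e-04 to 0.591 and 0.00277 to 0.537. The negative control spots, which were used only for an alternative filter on dim probes, lay above the blank spots on every array. The distance was 2.00 intensity units on the lowest and 3.73 on the highest, and on each array it was more than 2 SD of the blanks.

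The Tbx6 probe was not higher with Dox at day 2 although 2557 probes changed. A single mislabelled array at day 2 is argued against, since every day-2 array correlated better with its own partner than with any array of the other Dox state, by at least 0.00850, but an exchange of both pairs would leave this value as it is and stays open. A general stress of the cells by Dox was judged at day 2 by the ATF4 response genes alone. Their median log2 change of -0.33 (0 of 14 rose, 3 fell) argues against a rise of that response there. It cannot exclude other kinds of stress. In the heat shock and unfolded protein response list 4 of 13 rose and 3 fell at day 2, and both Hspa8 probes rose (0.80 and 0.99). At day 4 the ATF4 genes were higher with Dox (median 1.23). Whether the probe reports the transgene cannot be told apart from a transgene that was not induced, because its position in the transcript is unknown and its change was -0.20 at day 2. A probe outside the inserted sequence may then have risen at day 4 through the cell's own gene.

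By camera with the preset correlation, the hypoxia and glycolysis list was lower with Dox at day 2 and higher at day 4, but it passed at neither day with an estimated correlation (adjusted p = 0.0655 and 0.0942). Between-array scaling is argued against, since under the 3 other scalings the median stayed at or below -1.09 at day 2 and at or above 0.53 at day 4, and a shift of all bright probes is argued against too, with 0% at day 2 and 0.01% at day 4 of 10000 random lists matched on brightness having a median as far from 0, although such lists take genes as independent. The oxygen response of the cultures may differ between the groups, and this cannot be told apart from other causes, because HIF targets outside the list and not noticed before had a median of -0.46 at day 2 (2 of 22 rose, 11 fell, camera p = 1.5e-06, adjusted p = 8.7e-06, and p = 0.00608 with an estimated correlation) and of -0.11 at day 4 (3 rose, 6 fell, camera p = 0.271, adjusted p = 0.271, and p = 0.292 with an estimated correlation). With the 6 noticed before, of which Adm, Bhlhe40, Pgm2 and Vldlr rose at day 4, the median was -0.74 at day 2 (2 of 28 rose, 17 fell) and -0.06 at day 4 (7 rose, 6 fell). The rule written before the test counted a median at or below 0 at day 4 against a differing oxygen response. The median of -0.11 over the genes not noticed met that rule. Its approximate standard error over genes was 0.21, so day 4 does not settle the question.

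Pluripotency genes were far higher with Dox at day 4, and between-array scaling is argued against, since the lowest median under the 3 other scalings was 2.40. A remaining share of undifferentiated cells would make the naive genes fall alike from day 2 to day 4 with Dox, and the SD of their log2 changes was 1.23 over all 14 but 0.631 over the 9 not noticed before, on either side of the bound of 1 set for it. Over all 23 measured pluripotency genes, 14 fell and 2 rose past the threshold, from -3.17 (Nr0b1) to 1.06 (Tdgf1), and their SD of 1.36 against a median SE of 0.137 goes against a uniform fall. Since only 4 lay above 0, under the share of 1 in 4 that would have excluded it, and the naive genes lay on both sides of their bound, such a share of cells cannot be told apart from other causes. A slower exit from pluripotency under Dox may hold as well and was not tested apart.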

How the results depend on the processing

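The scanner-gain block, the crossed pairing, normexp on the blank spots and the negative control filter were tests chosen only after the result was seen. Over the other scalings, sources, background settings, filters, blocks and variance settings of all 8 arrays except normexp on the local background, the counts ran from 2009 to 3327 for Dox at day 2 and from 4673 to 7169 at day 4. With normexp on the local background, limma called 2 probes for Dox at day 2, 0 at day 4, 0 for the difference, 0 over time without Dox and 3 with Dox (479, 854, 527, 607 and 781 at an unadjusted p under 0.05). Camera then called 3, 2 and 3 lists for the first 3 comparisons, and the overlap held 0 probes. That column carries the spot's own signal (correlation of logs 0.984 to 0.998). A fit of only the 4 day-2 arrays, which leaves fewer arrays to estimate the spread, called 1632 probes. A minimum change of 2-fold left 760, 2371, 2695, 3290 and 1451 probes in the 5 comparisons and an overlap of 248, and an adjusted p under 0.01 left 1150, 3947, 2640 and 2197 in those other than time without Dox. With the scanner gain as a block, which shares its split with time under Dox, 1342 probes passed for that comparison. With an estimated correlation camera called 0 lists at day 2, 2 at day 4 and 1 for the difference (fry 19, 26 and 30).

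Leaving out 1 array leaves its group with a single array that is assumed to vary like the others. Calls then ranged over 1191 to 2282 for Dox at day 2, 4620.0 to 6133 at day 4, 3475 to 3896 for the difference, 6456 to 8017 without Dox and 2419 to 3845 with Dox over time, 9 to 12, 18 to 19 and 15 to 20 lists, and an overlap of 481 to 759. The lowest counts at day 2 came without any 1 of the 4 day-2 arrays (1267, 1191, 1332 and 1541).

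With the replicate number as a block, 2009, 5915, 4154, 7754 and 3545 probes passed in the 5 comparisons, with 12, 18 and 17 lists and an overlap of 759. The calls of Aurka, Ccnb2 and Ocln at day 2 and of the BMP list for the difference ended under the block, and that of the fibroblast list at day 2 appeared. The numbers do not pair the samples, because correlations of the replicate differences between groups ran from -0.27 to 0.23 and no label ties them. The crossed pairing at day 2, where the correlation was -0.20, called 824 probes in a fit of the 4 day-2 arrays, against 126 with the pairing as labelled.

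The direction turned under normexp on the local background for lists and genes as follows, each with its value there, and the cause was not tested. Lists with a turned test were neural (0.0057) and housekeeping (0.14) at day 2, BMP pathway and targets (-0.019), cell cycle (-0.023) and cholesterol synthesis (0.070) at day 4, and pluripotency (-0.055), cell cycle (0.017) and cholesterol synthesis (0.089) for the difference. Genes at day 2 were Cd37 (-0.017), Cldn7 (0.12), Fabp7 (0.010), Gata6 (0.011), Hspb1 (-0.045), Izumo1r (0.0089), Ly6c1 (-0.18), Pax6 (0.036), Pdgfra (0.0072), Rhox6 (-0.26), Tpi1 (0.12) and Ttr (0.031). Genes at day 4 were Acta2 (-0.048), Ap1m2 (-0.10), Chac1 (-0.29), Cnn1 (-0.11), Crabp2 (0.80), Cxcr4 (0.0042), Dll1 (0.038), Dll3 (-0.080), Epcam (-0.47), Epha1 (-0.23), Hes5 (0.085), Hspb1 (-0.23), Mixl1 (-0.0066), Myl7 (-0.017), Nanog (-0.64), Pdgfra (-0.0041), Rrm2 (1.26) and Tbx6 (-0.057). Over time they were Sycp3 (0.10) without Dox and Cd37 (0.0049), Folr1 (0.17) and Zscan4c (0.066) with Dox. The adjusted p of these genes was 0.999 or more. Fry gave the trophoblast list the opposite direction to camera for the difference (median -0.10, adjusted p = 0.0307 against 0.668 by camera).

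Under all alternatives together, the lists kept direction and side of the threshold in 2248 cases, lost it in 113, gained it in 72 and turned in 9, and the named genes in 3374, 168, 5 and 34. Of the 168 losses, 125 came with normexp on the local background. The deposited values and the scanner-gain block ended 2 named-gene calls each. Scaling to the 75th percentile, no filter on dim probes and normexp on the blank spots ended 1 each. Signal over background limits dim probes, since 86.0% to 89.2% of gene probes were above the blanks on an array. Not run were quantile normalization as an alternative, since it was used throughout, normexp with offset 16, and a block on slide or scan date, which were not used here.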

Other observations

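The gene lists of this part were written after the first results were seen, the genes noticed by then were left out of their tests, and the genes named here were chosen after their values were seen. Dppa3, Tfap2c, Nanos3 and Bmp8b had drawn attention to primordial germ cells. Among 11 other genes of such cells, 5 rose and 0 fell with Dox at day 2 by limma (median log2 change 0.36, camera p = 0.00474, adjusted p = 0.00813, and p = 0.0415 with an estimated correlation, with Benjamini-Hochberg adjustment over 12 tests). Sox15, a Sox-family factor gene, rose by 2.44 ± 0.18, whereas the germ cell genes Dazl (-0.52 ± 0.23), Ddx4 (-0.04 ± 0.11) and Dnd1 (-0.16 ± 0.11) did not pass the threshold. Dazl passed as lower without DoxOFF_day4 replicate 1 or 2 (adjusted p = 0.0383 and 0.0385), with the scanner-gain block, with no background correction and with normexp on the blank spots. At day 4 the median was 0.25 (camera p = 0.0830, adjusted p = 0.0906, and p = 0.143 with an estimated correlation). Among 9 naive pluripotency genes not noticed before, 4 rose and 0 fell at day 2 (median 0.49, camera p = 2.8e-06, adjusted p = 1.1e-05, and p = 0.00823 with an estimated correlation). The naive list shares genes with the pluripotency list, which had already passed at day 2, so this test is not separate support for that rise. The rise of germ cell genes was not tested apart from that of naive genes.

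Sycp3, Hormad1, Tdrd12, Gtsf1 and Rhox6 had drawn attention to the germline. Other meiosis and germline genes had a median log2 change of 0.51 with Dox at day 4, where 10 of 19 rose and 0 fell (camera p = 5.2e-06, adjusted p = 1.6e-05, and p = 0.0153 with an estimated correlation). At day 2 the median was -0.33 (camera p = 0.0473, adjusted p = 0.0631, and p = 0.152 with an estimated correlation). The recombinase gene Dmc1 rose by 2.08 ± 0.15 at day 4, and Mael, a transposon-silencing gene of the germline, changed by -1.70 ± 0.16 at day 2 and 1.80 ± 0.16 at day 4. From day 2 to day 4, 14 of the list's genes fell and 1 rose without Dox, and 12 fell and 1 rose with Dox. The difference of 0.51 at day 4 may thus reflect a smaller fall with Dox more than a gain.

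Genes of the ATF4 stress response had a median of -0.33 at day 2, where 0 of 14 rose and 3 fell (camera p = 0.0158, adjusted p = 0.0236, and p = 0.0622 with an estimated correlation). At day 4 the median was 1.23, and 12 rose and 0 fell (camera p = 4.5e-09, adjusted p = 5.4e-08, and p = 0.00336 with an estimated correlation). The factor gene Cebpb rose by 3.06 ± 0.12, the pseudokinase gene Trib3 by 1.79 ± 0.12 and the asparagine synthetase gene Asns by 1.76 ± 0.20. From day 2 to day 4, 11 of these genes fell and 0 rose without Dox, and 8 rose and 0 fell with Dox. Trib3 and Asns also stand in the heat shock and unfolded protein response list, which had passed at day 4. The ATF4 rise at day 4 is thus not separate from that list's rise.

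Irgm1 and Nmi were higher with Dox at both days, and an interferon response was tested as their source. The 17 other genes of the list had a median of 0.07 at day 2 (camera p = 0.0709, adjusted p = 0.0850, and p = 0.149 with an estimated correlation), which leaves it open there. At day 4 the median was 0.11, and 8 rose and 1 fell (camera p = 0.00214, adjusted p = 0.00429, and p = 0.0387 with an estimated correlation). The guanylate-binding protein gene Gbp2 rose by 3.70 ± 0.14 and the factor gene Irf1 by 2.75 ± 0.12 at day 4. From day 2 to day 4, 0 of the 17 other genes rose and 9 fell without Dox (median -0.42). With Dox, 2 rose and 6 fell (median -0.21). The difference at day 4 may thus reflect in part a smaller fall with Dox.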
